A study of Mus musculus with 9 samples.

How the data were processed

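The series holds RNA sequencing of lung tissue from 9 mice with LPS-induced acute lung injury, 4 without and 5 with TMAO. The labels name lung as the tissue and source, while the wording of their extraction protocol names platelets. The score of alveolar type 2 markers was 1.88 to 4.34 in every library and that of platelet genes -0.52 to 0.34, and the samples are treated as lung. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was depleted and libraries were made with a NEBNext Ultra II kit. Per the submitters' processing notes, the tools were fastp, HISAT2, SAMtools and featureCounts, with no versions given, and the genome build was mm10. The role of each tool, the annotation, the strand setting and the gene lengths used are not given in the sources used here. The deposited values are FPKM, fragment counts scaled to gene length and sequencing depth, made by the authors and rounded to 2 decimals, with 1 column per library and no pooling. No column was left out.

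Samples were grouped by the sample group in the labels, and the titles number the mice within a group. The group coded LPS-ALI has 4 mice and the group coded TMAO has 5. The library codes, which begin with B or X, come from the sample descriptions, and their meaning is not given in the sources used here. Gene identifiers were matched to GENCODE M21 on GRCm38, the same assembly as mm10, and 52073 of 52381 matched. Coordinates, gene types, exon lengths and GC shares come from that annotation. Where several genes shared a symbol, the gene with the highest mean was used.

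FPKM values are not counts, so no count model was used. Values were tested as log2(FPKM + 1), which understates the change of low genes, over 11817 genes with FPKM of at least 1 in at least 4 libraries. The difference is TMAO minus LPS-ALI. Genes were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, two-sided, and with Benjamini-Hochberg adjustment and a threshold of 0.05. Vav3 and the list scores were also tested by exact two-sided permutation over all splits of the 9 libraries, for which the smallest p is 0.00794. A total of 42 gene lists for lung cell types, inflammation, stress and other pathways was fixed before the data were examined, as were the tests and all alternatives not described as added later. The 40 lists with at least 5 tested members were tested with limma's camera and a preset inter-gene correlation of 0.01, which compares a list with all other genes. The result of 1 of these lists is not reported here. The adipocyte and histone lists had 4 and 3 tested members and were not tested. Camera with an estimated correlation and fry were run beside it. A list score is the mean log2 value of the tested members minus the median tested gene of the same library.

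Genes were named by a rule fixed before the data were examined. It takes Vav1, Vav2 and Vav3, then, among genes with a symbol and a mean FPKM of at least 1, those past the threshold with no overlap between the groups, up to the 10 largest and the 10 smallest log2 differences. Where fewer than 5 pass in a direction, it takes the 5 genes with the smallest unadjusted p in that direction. It adds up to 4 members with the smallest unadjusted p from each list described. No gene passed the threshold, so the 5 smallest p per direction were used, and these genes are described by their values. S100a8 and S100a9, Ddx3y and Xist were added after the data were seen.

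Read totals are not given. Where a gene holds few reads, its FPKM in different libraries is a small multiple of what 1 read is worth, so the commonest ratio between libraries over genes with a value in at most 5 libraries estimates their relative depth. The fitted depths matched the commonest ratio within 0.1 log2 units in 35 of 36 library pairs. Absolute depth, and therefore counting intervals, stay unknown. No library was a copy of another, since a pair had the same value for at most 63 of the 11817 tested genes. In simulated data with the residual spread of the 11817 real genes, limma called 2% of 100 genes changed 2-fold and 54% of 100 genes changed 4-fold in this comparison. It called 5 unchanged genes there, and 0 genes and 0 lists when nothing was changed. Simulated genes varied independently, which real genes of a pathway do not.

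The alternatives were pseudocounts of 0.1 and 0.5, no filter and a mean FPKM of at least 5, rescaling to TPM, median-of-ratios and quantile scaling, and removal of mitochondrial, haemoglobin and small RNA genes. The variance model was also run without trend, with robust moderation and with library weights. Further alternatives were the mouse number as a replicate block, other thresholds, and leaving out each library or the X-coded libraries. After the data were seen, exact permutation of list scores and the joint removal of the X-coded libraries or LPS-ALI replicate 4 with TMAO replicate 5 were added. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.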

Results

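Gene expression was measured by RNA sequencing in the lungs of mice with acute lung injury (ALI) caused by lipopolysaccharide (LPS), a component of the bacterial outer membrane that sets off acute inflammation. The 9 libraries, each from a separate mouse, fall into 4 lungs with LPS injury alone, called LPS-ALI here, and 5 lungs from injured mice that were also given trimethylamine N-oxide (TMAO), a metabolite made from gut bacterial products. Mice without LPS are not analysed here. The deposited FPKM values covered 52381 genes, of which 15527 to 19196 were above 0 in a library. Genes of the mitochondrial genome held 33.4% to 52.2% of the FPKM of a library, and the top 10 genes held 41.2% to 66.9%. TMAO replicate 5 had the highest of both shares. Read totals are not given, but the spacing of low values gave relative depths of 0.495, 0.751, 1 and 0.770 for LPS-ALI replicates 1 to 4. The corresponding depths were 0.680, 0.621, 0.683, 0.654 and 0.381 for TMAO replicates 1 to 5.

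The alveolar type 2 marker score lay 1.88 to 4.34 log2 units above the median gene in the 9 libraries, Ddx3y from the Y chromosome had 4.09 to 28.6 FPKM, and Xist was at most 0.01, so the libraries did not differ in sex. Among them 2 libraries stood apart from the rest. TMAO replicate 5, the shallowest, held 8846 genes with FPKM of at least 1 against 11158 to 12239 in the others, and it lay farthest from the rest on the leading principal component, which carried 53.2% of the variance. LPS-ALI replicate 4 lay farthest on the next component, with 19.98%. It held the lowest alveolar type 2 score, 1.88, against 3.51 to 4.34 in the others. Its endothelial and capillary, fibroblast and smooth muscle scores were also the lowest, at 1.01, 0.27 and -0.79. Its ciliated cell and type I interferon scores were the highest, at 1.35 and 3.38. Its median correlation with the other libraries was 0.890, against 0.895 for TMAO replicate 5 and 0.929 or more for the remaining 7. The library codes of LPS-ALI replicates 3 and 4 begin with X and those of the other 7 with B, so this code occurs with X in the LPS-ALI group only. The numbers after the B are consecutive in the TMAO libraries, and the B-coded LPS-ALI libraries lie outside that run. Leaving out the X-coded libraries therefore does not make the groups alike in code.

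**Figure D1:**
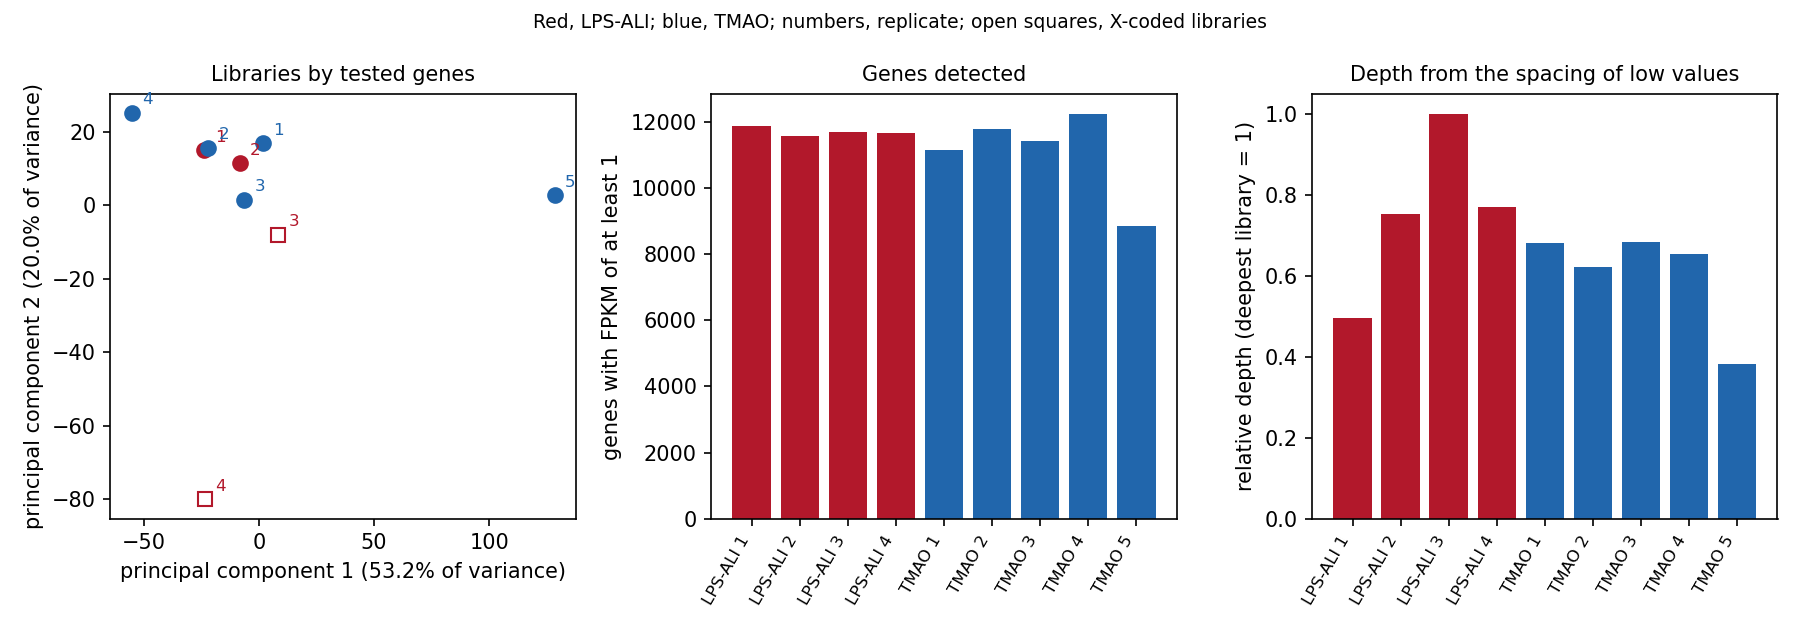
Principal components of log2(FPKM + 1) over the 11817 tested genes (left, points are libraries), genes with FPKM of at least 1 (middle, bars) and relative depth with the deepest library at 1 (right, bars). TMAO replicate 5 lies far along component 1 and has 8846 detected genes and a relative depth of 0.381, while LPS-ALI replicate 4 lies at the low end of component 2.

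The comparison of TMAO with LPS-ALI lungs asks what TMAO changes in the injured lung. TMAO lungs had lower levels of immediate early genes, LPS-induced cytokines and chemokines, and acute-phase genes, taken as groups and relative to all other genes. The mean log2 difference from all other genes was -0.71 for immediate early genes, -0.65 for cytokines and -0.46 for acute-phase genes. All 3 groups passed limma camera with a preset correlation but not with an estimated one (limma camera adjusted p = 0.516, 0.516 and 0.529), under which 0 of 40 lists passed. Endothelial and capillary markers were 0.70 log2 units higher, a difference that also passed only with the preset correlation (limma camera adjusted p = 0.535 with an estimated one) and was 0.06 without the LPS-ALI libraries coded X. Vav3, the gene in the title of the series, had higher mean FPKM in TMAO lungs without passing its test. No single gene of 11817 passed an adjusted p of 0.05 by limma, and the smallest adjusted p was 0.382. At an unadjusted p under 0.05, limma gave 396 genes, 50 higher and 346 lower, where chance alone would give 591. With median-of-ratios scaling that split became 356 higher and 441 lower, and with quantile normalization 441 higher and 450 lower. Without TMAO replicate 5 it turned to 505 higher and 355 lower, 860 genes in all. Without LPS-ALI replicate 3 the count past the adjusted threshold was 1, and without TMAO replicate 4 it was 3. The median tested gene was shifted by -0.17 log2 units in TMAO lungs, a shift that shrank to -0.01 under median-of-ratios scaling. Without TMAO replicate 5 the shift turned to 0.05, so it rests on that library. Log2 differences are therefore given below relative to the median gene unless marked unshifted.

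Vav3 encodes a guanine nucleotide exchange factor of the Vav family. The gene (ENSMUSG00000033721) lies on chromosome 3 from 109340653 to 109685698 of GRCm38, on the plus strand. Its FPKM was 3.04 ± 1.05 (SD, n = 4) in LPS-ALI and 5.03 ± 1.38 (SD, n = 5) in TMAO lungs. The log2 difference was 0.75 relative to the median gene. Unshifted it was 0.58 ± 0.33 (SE), with an exact two-sided permutation p of 0.0556 over all splits of the 9 libraries and a limma adjusted p of 0.998. Single values overlapped, since LPS-ALI replicates 1 and 2 had 3.67 and 4.19 and TMAO replicate 3 had 3.49. The X-coded libraries had the lowest values, 2.25 and 2.07, and without them the relative difference was 0.48 (unshifted 0.26, exact permutation p = 0.381). Under median-of-ratios scaling the relative difference was 0.78 (unshifted 0.77, exact permutation p = 0.0238) and under quantile normalization 0.74 (unshifted 0.75, exact permutation p = 0.0317), while with library weights it was 0.24 (unshifted 0.22). The unshifted exact permutation p was 0.0357 without LPS-ALI replicate 2 and 0.0286 without TMAO replicate 3. Without TMAO replicate 5, on which the shift of the median gene rests, the relative difference was 0.57 (unshifted 0.62, exact permutation p = 0.0857). Without LPS-ALI replicate 4 as well, it was 0.40 (unshifted 0.50, exact permutation p = 0.143). Vav1, the haematopoietic family member, averaged 9.39 ± 6.20 FPKM in LPS-ALI and 6.16 ± 2.40 in TMAO lungs, with 18.65 in LPS-ALI replicate 3 and 5.60 to 7.06 in the other LPS-ALI libraries. Vav2 averaged 1.43 ± 0.72 and 1.51 ± 0.99.

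**Figure D2:**
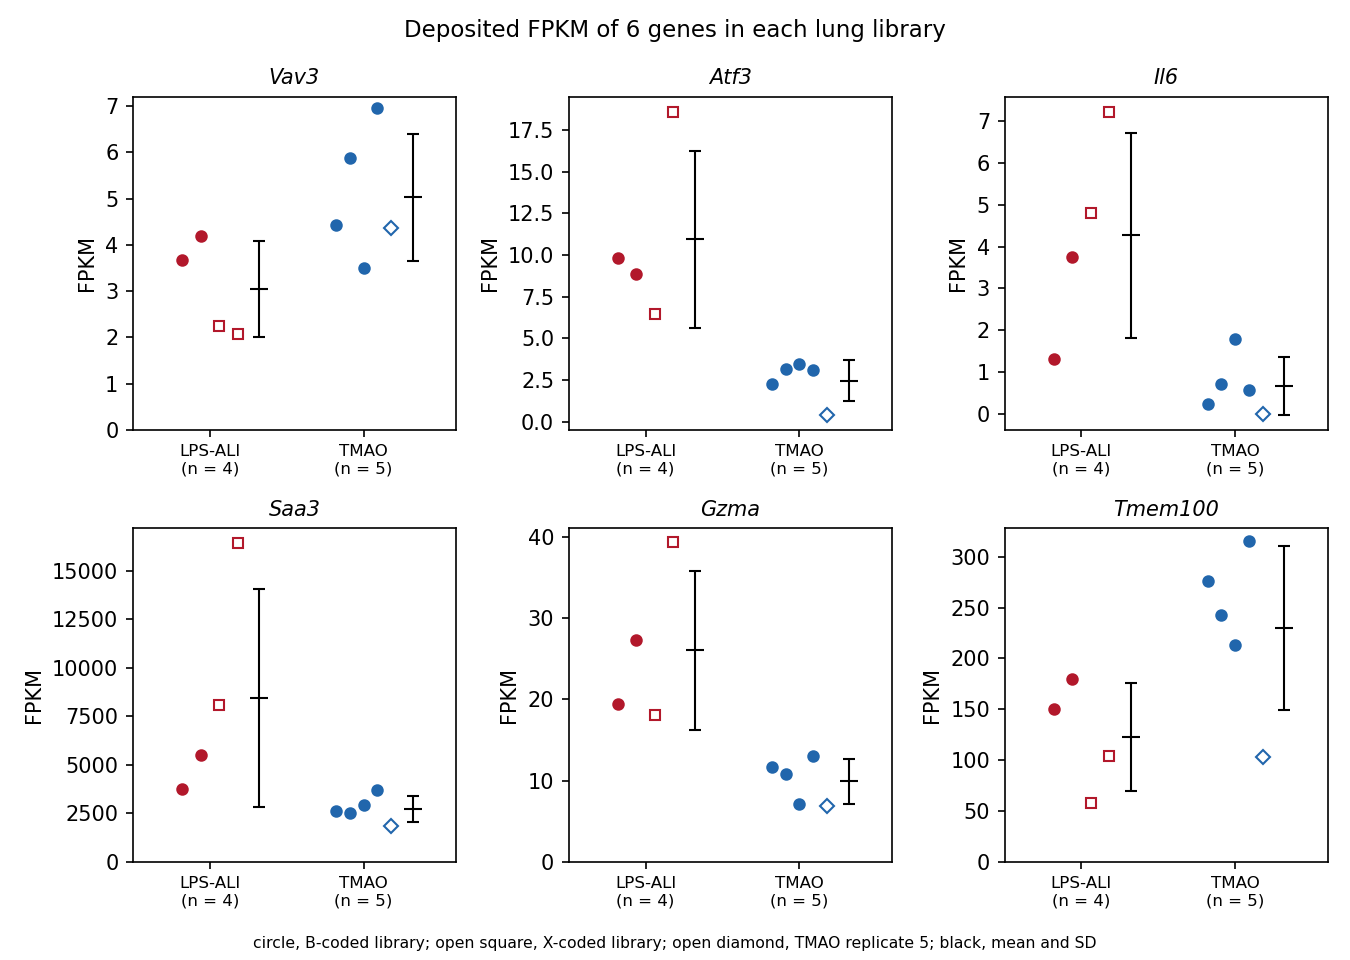
FPKM of 6 genes in each library of the LPS-ALI and TMAO groups, with points for libraries and black marks for the mean and SD. Atf3, Saa3 and Gzma show no overlap between the groups, while Vav3, Il6 and Tmem100 do.

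The 5 genes with the smallest p among those lower in TMAO lungs were Rasd1, Vpreb3, Atf3, Il6 and Saa3, none past the threshold. Rasd1, a dexamethasone-inducible Ras-related gene on chromosome 11 (59963181 to 59964944), had 6.13 ± 4.82 FPKM in LPS-ALI and 0.436 ± 0.242 in TMAO lungs, a relative log2 difference of -1.96 (limma adjusted p = 0.382). Vpreb3, a B-lineage gene, had 6.72 ± 1.73 and 1.81 ± 0.89 FPKM (relative difference -1.32). Atf3, a stress-induced transcription factor gene on chromosome 1 (191170296 to 191218039), had 10.9 ± 5.30 and 2.48 ± 1.22 FPKM (relative difference -1.62). Il6, for a cytokine that drives the acute-phase response, lies on chromosome 5 (30013114 to 30019981) and had 4.27 ± 2.46 and 0.662 ± 0.685 FPKM (relative difference -1.44). Saa3, a serum amyloid gene on chromosome 7 (46711998 to 46715700), had 8456 ± 5632 and 2711 ± 677 FPKM (relative difference -1.29). For these last 4 genes the limma adjusted p was 0.998. Each of the 5 genes with the smallest p among those higher in TMAO lungs was listed at 0 in at least 1 LPS-ALI library (limma adjusted p = 0.998 each). Gm6361 and Gm6029 are processed pseudogenes whose reads can be shared with parent genes, and Gm44170 is antisense to other transcripts with no strand setting stated. Gm6361 was listed at 0 in all 4 LPS-ALI libraries and in TMAO replicate 4, with 5.07 to 20.76 FPKM in the other TMAO libraries. Gm6029 had 0 to 1.24 FPKM in LPS-ALI and 1.35 to 4.65 in TMAO lungs. Tmsb15b2, a thymosin beta gene, and Gm44170 were at 0 in 3 LPS-ALI libraries, with 1.74 and 7.32 FPKM in replicate 3, against 1.37 to 11.31 and 3.02 to 8.90 in TMAO lungs. The processed transcript 2500002B13Rik had 0 to 2.49 FPKM in LPS-ALI and 2.81 to 11.98 in TMAO lungs. Across all genes, 175 had no overlap between the groups, 161 of them lower in TMAO, which is 1.48% of those tested against 1.59% expected by chance. The FPKM values behind this count were not corrected for the shift of the median gene.

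Immediate early genes, which are transcribed within minutes of a stimulus, had the smallest limma camera p with the preset correlation among the lists. Of 17 tested members 15 lay below the median gene, 6 passed adjusted over the list alone, and 0 passed over all genes tested. Fos had 57.9 ± 19.9 FPKM in LPS-ALI and 21.2 ± 14.6 in TMAO lungs. Egr1 had 39.6 ± 9.89 and 13.6 ± 10.9 FPKM, and the phosphatase gene Dusp1 had 154 ± 30.4 and 71.2 ± 45.6. The list score, the mean log2 value of the members minus the median gene of the library, was lower in all 5 TMAO lungs than in any LPS-ALI lung. The score difference was -0.71, with an exact permutation p of 0.0159 (adjusted p = 0.190 over 40 lists). The limma camera adjusted p was 7.55e-09 with a preset correlation, and the call was lost at an adjusted p = 0.516 with an estimated correlation.

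LPS-induced cytokines and chemokines were lower in TMAO lungs, with 21 of 23 tested members below the median gene and 1, Il6, past the threshold adjusted over the list alone. Ccl20, a chemokine for CCR6-bearing lymphocytes and dendritic cells, had 3.09 ± 1.19 and 0.982 ± 0.811 FPKM. Il1a had 2.78 ± 1.40 and 1.11 ± 0.49 FPKM, and the anti-inflammatory Il10 had 5.88 ± 4.79 and 1.84 ± 1.78. The score difference was -0.65 (exact permutation p = 0.0238), and 4 of 5 TMAO lungs lay below every LPS-ALI lung. Over 40 lists the adjusted exact permutation p was 0.190. LPS-ALI replicate 4 scored 1.62 and the other LPS-ALI libraries 0.67 to 0.91, and without it the score difference was -0.45 (exact permutation p = 0.0714). The exact permutation p was 0.0571 without any one of TMAO replicates 1 to 4. The limma camera adjusted p was 6.41e-08 with a preset correlation and the adjusted p = 0.516 with an estimated correlation. Acute-phase and inflammasome genes had a score difference of -0.46, with all 5 TMAO lungs below every LPS-ALI lung (exact permutation p = 0.00794, the smallest that these groups can give). Of its 19 tested members 17 lay below the median gene, among them Pycard, the inflammasome adaptor, with 22.7 ± 10.5 and 8.78 ± 4.75 FPKM. Lcn2, the siderophore-binding lipocalin, had 2716 ± 1575 and 1464 ± 517 FPKM, and Orm1 had 48.8 ± 56.6 and 14.8 ± 4.29. LPS-ALI replicate 4 had 4946 FPKM for Lcn2 and 133 for Orm1, and without it their unshifted log2 differences of -0.80 and -1.12 were -0.46 and -0.44. That of Pycard was -1.53, and -0.91 without TMAO replicate 5. The limma camera adjusted p was 5.59e-06, with adjusted p = 0.529 with an estimated correlation. Genes of the Toll-like receptor and NF-kB pathway, upstream of these cytokines, had a score difference of -0.21 (limma camera adjusted p = 0.0314, and adjusted p = 0.729 with an estimated correlation). That call ended without the X-coded libraries (limma camera adjusted p = 0.0621) and without any of LPS-ALI replicates 1, 2 and 4 and TMAO replicates 1 and 5 (0.0579 to 0.204), in a range over all alternatives of 0.00746 to 0.475, and without LPS-ALI replicate 4 the score difference was -0.13.

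**Figure D3:**
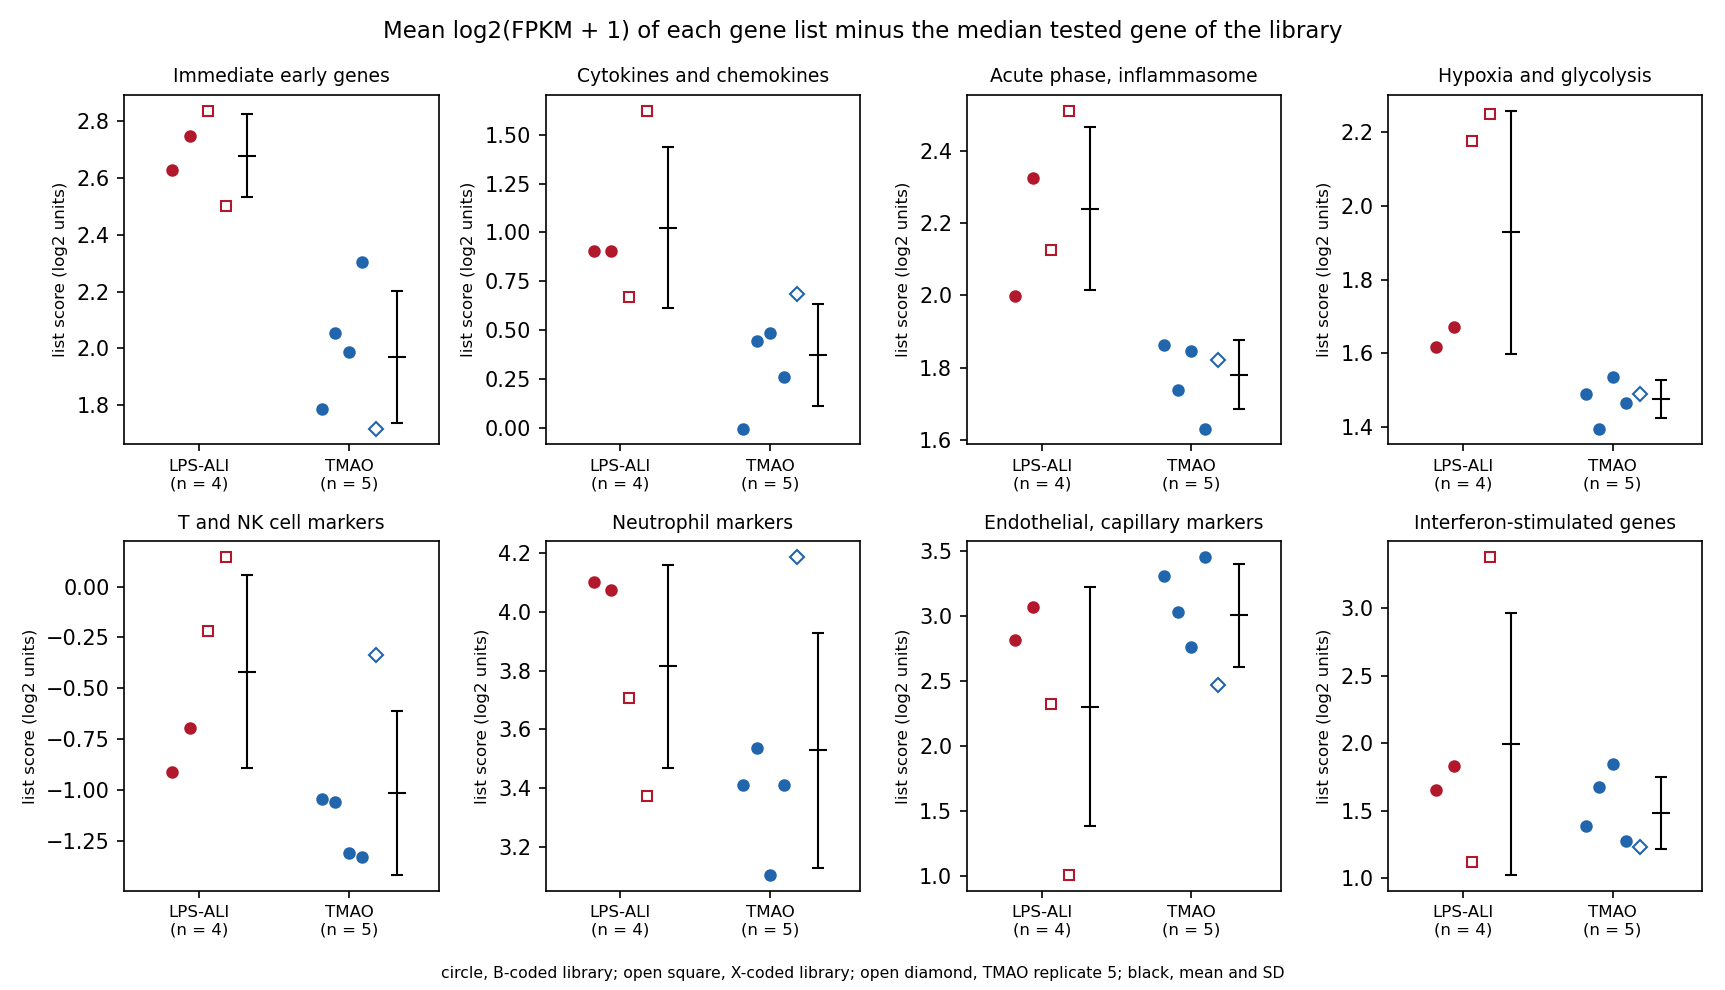
Score of 8 gene lists in each library, on the vertical axis in log2 units relative to the median tested gene, for 4 LPS-ALI and 5 TMAO lungs, with black marks for the mean and SD. All 5 TMAO lungs lie below every LPS-ALI lung for immediate early, acute-phase and hypoxia lists, whereas the endothelial scores differ mainly through the X-coded libraries.

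Hypoxia and glycolysis genes had a score difference of -0.45, again with all 5 TMAO lungs below every LPS-ALI lung (exact permutation p = 0.00794). Hexokinase gene Hk2 had 5.00 ± 1.70 FPKM in LPS-ALI and 2.01 ± 0.77 in TMAO lungs, Hif1a had 34.1 ± 16.9 and 14.7 ± 7.18, and Gapdh had 806 ± 318 and 452 ± 101. The limma camera adjusted p of 9.08e-06 went to an adjusted p = 0.547 with an estimated correlation and to 0.0672 without the X-coded libraries, in a range over all alternatives of 3.67e-06 to 0.129. The hypoxia score difference was -0.17 without the X-coded libraries. ER stress and chaperone genes had a score difference of -0.33 (limma camera adjusted p = 0.00328, and adjusted p = 0.616 with an estimated correlation). Besides Atf3, the members with the smallest p were Atf4, with 224 ± 155 and 95.2 ± 38.7 FPKM, and Herpud1, with 35.4 ± 11.8 and 20.1 ± 3.87. Glucocorticoid-responsive genes had a score difference of -0.62, with Errfi1, Dusp1 and the metallothioneins Mt1 and Mt2 past the threshold adjusted over the list alone (4 of 14) and 0 over all genes tested. Mt1 had 1312 ± 1606 FPKM in LPS-ALI, where replicate 4 alone had 3694, and 226 ± 91.2 in TMAO lungs. Without LPS-ALI replicate 4 the unshifted log2 differences of Mt1, Mt2 and Atf4 were -1.13, -1.18 and -0.73, in place of -1.87, -1.94 and -1.14. The limma camera adjusted p of this list was 2.77e-05, with adjusted p = 0.547 with an estimated correlation and 0.0549 without the X-coded libraries (range over all alternatives 2.11e-07 to 0.307). Its score difference was -0.33 without LPS-ALI replicate 4 and -0.20 without the X-coded libraries. Antioxidant and Nrf2 target genes, which share the metallothioneins, had a score difference of -0.37 (limma camera adjusted p = 0.00477, and adjusted p = 0.616 with an estimated correlation). Their call ended without LPS-ALI replicate 4 (limma camera adjusted p = 0.234), the library with the highest score at 4.13, where the score difference was -0.10, without the X-coded libraries (0.237) and under median-of-ratios scaling (0.0612), in a range over all alternatives of 0.000388 to 0.237.

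Mean scores of several leukocyte marker lists were lower in TMAO lungs. Of these lists, only the monocyte list had an exact permutation p under 0.05, and its adjusted exact permutation p was 0.190. The exact permutation p was 0.0873 for T and NK cell markers and 0.0635 for B and plasma cell markers. For neutrophil and alveolar macrophage markers the exact permutation p was 0.270 and 0.222. T and NK cell markers had a score difference of -0.59, and 4 of 8 tested members passed adjusted over the list alone, 0 over all genes tested. The cytotoxic granule genes Gzma and Gzmb had 26.1 ± 9.81 and 11.8 ± 10.8 FPKM in LPS-ALI, and 9.90 ± 2.73 and 2.30 ± 0.40 in TMAO lungs, with no overlap between the groups. The limma camera adjusted p was 5.61e-05, with adjusted p = 0.516 with an estimated correlation and 0.0790 without the X-coded libraries (range over all alternatives 4.02e-06 to 0.0790). The T and NK score difference was -0.21 without the X-coded libraries. TMAO replicate 5 had a score of -0.34, within the LPS-ALI range, while the other TMAO lungs had -1.33 to -1.05. Neutrophil markers had a score difference of -0.29 (limma camera adjusted p = 0.00313, and adjusted p = 0.547 with an estimated correlation), and 6 of 18 members lay above the median gene. Camp and Ngp, genes of late granulocyte precursors, were the 2 members past the threshold adjusted over the list alone. Camp had 34.8 ± 19.96 and 9.29 ± 2.44 FPKM, and Ngp had 343 ± 139 and 134 ± 44.1. TMAO replicate 5 had the highest neutrophil score of all libraries at 4.19, and the neutrophil call ended under median-of-ratios scaling (limma camera adjusted p = 0.0895), without LPS-ALI replicate 1 (0.0739) and without TMAO replicate 3 (0.0749), in a range over all alternatives of 3.79e-13 to 0.0895. The neutrophil score difference was -0.19 and -0.43 without LPS-ALI replicates 1 and 4, and -0.18 and -0.45 without TMAO replicates 3 and 5. B and plasma cell markers, with Igkc at 32.3 ± 17.1 and 10.4 ± 5.04 FPKM, had a score difference of -0.48 over 5 tested members (limma camera adjusted p = 0.00728, and adjusted p = 0.516 with an estimated correlation). Monocyte and interstitial macrophage markers had a score difference of -0.18 (exact permutation p = 0.0238, and 0.0536 to 0.0893 without any one of LPS-ALI replicates 2 and 3 and TMAO replicates 1, 3, 4 and 5), with Vcan at 2.91 ± 0.77 and 0.890 ± 0.717 FPKM and Ly6c2 at 46.9 ± 18.6 and 24.3 ± 5.84. Their limma camera adjusted p was 0.0325, with adjusted p = 0.616 with an estimated correlation and 0.0965 without the X-coded libraries. It was 0.0808, 0.15 and 0.108 without LPS-ALI replicates 2 and 3 and TMAO replicate 4, and 0.101 and 0.0510 under median-of-ratios and quantile scaling (limma camera, range over all alternatives 0.00933 to 0.407). Alveolar macrophage markers had a score difference of -0.28 (limma camera adjusted p = 0.0193, and adjusted p = 0.616 with an estimated correlation), and the call ended without LPS-ALI replicate 4 (0.423), without TMAO replicate 4 (0.105) and without the X-coded libraries (0.965), in a range over all alternatives of 0.00235 to 0.965. Their score difference was -0.43 without LPS-ALI replicate 1 and -0.10 without LPS-ALI replicate 4. Proliferation genes had a score difference of -0.30 (limma camera adjusted p = 0.000953, and adjusted p = 0.516 with an estimated correlation). Without LPS-ALI replicate 3 it was -0.17 (limma camera adjusted p = 0.0484, range over all alternatives 5.51e-05 to 0.0484).

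Interferon-related genes were lower in TMAO lungs, and LPS-ALI replicate 4 had the highest scores. LPS-ALI replicate 3 had the lowest scores of all libraries, 1.12 for type I and 2.06 for interferon-gamma genes. No TMAO lung therefore lay below every LPS-ALI lung (exact permutation p = 0.333 and 0.127). Type I interferon-stimulated genes had 23 of 24 members below the median gene and a score difference of -0.51 (limma camera adjusted p = 4.99e-05, and adjusted p = 0.616 with an estimated correlation). LPS-ALI replicate 4 scored 3.38 and the other LPS-ALI libraries 1.12 to 1.83, and without it the score difference was -0.050 (limma camera adjusted p = 0.637, range over all alternatives 9.38e-11 to 0.883), while it was -0.80 without LPS-ALI replicate 3. Isg15 had 260 ± 282 and 89.1 ± 41.4 FPKM. Interferon-gamma and antigen presentation genes had a score difference of -0.43 (limma camera adjusted p = 0.000275, and adjusted p = 0.616 with an estimated correlation). Without LPS-ALI replicate 4 it was -0.19 (limma camera adjusted p = 0.0452) and without LPS-ALI replicate 3 it was -0.68, and the call ended without LPS-ALI replicate 4 and TMAO replicate 5 (limma camera adjusted p = 0.123, range over all alternatives 1.17e-09 to 0.123). Irf8, a myeloid transcription factor in that list, had 10.6 ± 9.90 and 3.57 ± 1.80 FPKM, with 25.4 in LPS-ALI replicate 4. Without that library the unshifted log2 differences of Isg15 and Irf8, -1.14 and -1.15 over all libraries, were -0.48 and -0.65, and that of Isg15 was -0.72 without TMAO replicate 5.

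Endothelial markers were higher in TMAO lungs relative to other genes, with 17 of 20 pan-endothelial and capillary members above the median gene and 0 past the threshold, adjusted over the list alone or over all genes tested. Tmem100 had 123 ± 53.1 FPKM in LPS-ALI and 230 ± 80.5 in TMAO lungs, Ramp2 had 246 ± 151 and 393 ± 114, and the transcription factor gene Sox18 had 44.0 ± 28.1 and 79.1 ± 32.4. Without LPS-ALI replicate 4 the unshifted log2 differences of Ramp2 and Sox18, 1.03 and 1.16, were 0.30 and 0.37, and that of Tmem100, 0.93, was 0.61 without LPS-ALI replicate 3. The score difference was 0.70 (exact permutation p = 0.143), and the limma camera adjusted p was 2.02e-08 with adjusted p = 0.535 with an estimated correlation. LPS-ALI replicates 3 and 4, coded X, scored 2.32 and 1.01, and LPS-ALI replicates 1 and 2 scored 2.82 and 3.07, within the range of the TMAO lungs. Without the X-coded libraries the score difference was 0.06 (exact permutation p = 0.952, limma camera adjusted p = 0.264, range over all alternatives 3.37e-11 to 0.264), and without LPS-ALI replicate 4 alone it was 0.27. Aerocyte markers, from the gas-exchange capillary cell, had a score difference of 0.33 (limma camera adjusted p = 0.00728, and adjusted p = 0.616 with an estimated correlation), which ended without the X-coded libraries (0.819) and without LPS-ALI replicate 3 (0.140, with a score difference of 0.20), in a range over all alternatives of 0.00116 to 0.819. Endothelial junction and barrier genes had a score difference of 0.22 (limma camera adjusted p = 0.0314, and adjusted p = 0.729 with an estimated correlation), while the median of their unshifted log2 differences was -0.02. That call ended without the X-coded libraries (limma camera adjusted p = 0.845), where the score difference turned to -0.019, without any of LPS-ALI replicates 3 and 4 and TMAO replicates 1, 3 and 4 (0.0551 to 0.325), and under median-of-ratios (0.0533) and quantile scaling (0.0510), in a range over all alternatives of 0.000425 to 0.845. The score difference was 0.090, 0.12 and 0.37 without LPS-ALI replicate 4, TMAO replicate 4 and TMAO replicate 5.

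Fibroblast and matrix genes had a score difference of 0.40 (limma camera adjusted p = 0.000825, and adjusted p = 0.616 with an estimated correlation), but their 2 smallest p belonged to genes that moved apart. The methyltransferase gene Inmt had 455 ± 306 and 854 ± 195 FPKM, and the protease inhibitor gene Timp1 had 72.8 ± 40.1 and 26.9 ± 9.91. Without LPS-ALI replicate 4 the unshifted log2 difference of Inmt was 0.54 in place of 1.47. The fibroblast call ended without LPS-ALI replicate 4 (score difference 0.0051, limma camera adjusted p = 0.733) and turned without the X-coded libraries (0.886), in a range over all alternatives of 4.06e-05 to 0.886. Smooth muscle and pericyte markers had a score difference of 0.30 (limma camera adjusted p = 0.0157, and adjusted p = 0.631 with an estimated correlation), which ended without LPS-ALI replicate 4 (0.637, with a score difference of 0.064), without TMAO replicate 5 (0.0638), without the X-coded libraries (0.951, where the score difference turned to -0.026) and under median-of-ratios (0.126) and quantile scaling (0.121), in a range over all alternatives of 0.00372 to 0.951. Mitochondrially encoded genes had a score difference of 0.32 (limma camera adjusted p = 0.000364, and adjusted p = 0.616 with an estimated correlation), which ended without TMAO replicate 5 (0.982), whose score was 13.4, without LPS-ALI replicate 4 (0.637) and under median-of-ratios (0.119) and quantile scaling (0.121), in a range over all alternatives of 5.92e-14 to 0.982. The mitochondrial score difference was 0.53 and 0.12 without LPS-ALI replicates 3 and 4, and 0.63 and -0.025 without TMAO replicates 4 and 5. Ciliated cell markers, with Foxj1 at 7.53 ± 9.32 and 1.25 ± 0.63 FPKM and Cfap126 at 9.998 ± 6.56 and 2.84 ± 1.01, had a score difference of -0.81 (limma camera adjusted p = 6.87e-06, and adjusted p = 0.516 with an estimated correlation). LPS-ALI replicates 3 and 4 scored 0.89 and 1.35 against -0.46 in replicates 1 and 2, and the call ended without these X-coded libraries (limma camera adjusted p = 0.711, range over all alternatives 4.03e-08 to 0.711). Without LPS-ALI replicate 4 alone the ciliated score difference was -0.47, and the unshifted log2 difference of Foxj1 was -0.76 in place of -1.41. Nuclear-encoded oxidative phosphorylation genes had a score difference of -0.10 (limma camera adjusted p = 0.0269, and adjusted p = 0.729 with an estimated correlation), which ended under TPM (0.121), median-of-ratios (0.589) and quantile scaling (0.235), without the X-coded libraries (0.200) and without any of LPS-ALI replicates 2 and 4 and TMAO replicates 1 to 4 (0.0620 to 0.292), in a range over all alternatives of 0.000665 to 0.589. Its score difference was -0.14 and -0.030 without LPS-ALI replicates 1 and 4, and -0.046, -0.026 and -0.24 without TMAO replicates 2, 4 and 5.

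In all, 24 of 40 tested lists passed the limma camera threshold with the preset correlation, 6 higher and 18 lower. Other splits of the libraries gave a median of 14 lists with that setting. Some lists share members, so their calls are not independent. Immediate early genes share Atf3 with ER stress, Dusp1 with glucocorticoid-responsive and Nr4a1 with monocyte genes. Lcn2 is in the acute-phase, neutrophil and glucocorticoid lists, and Xbp1 in the ER stress and B cell lists. With an estimated correlation 0 passed (smallest adjusted p = 0.516), limma's fry gave 0 (smallest adjusted p = 0.265), and exact permutation of the list scores gave 0 after adjustment (smallest adjusted p = 0.159). The 16 lists that did not pass included alveolar type 2 cell markers (limma camera adjusted p = 0.114), club cell, mesothelial, lymphatic, platelet and erythroid genes, heat shock genes and circadian clock genes.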

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

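The sum over the repeat gene family was chosen only after its values were seen, while the other measures and the tests in this part were set before. The genes and lists examined were those named or called above, so they were picked from the same data. Over 168 groups of values, 19 had a library far from the rest of its group by Dixon's ratio, where chance gives about 1 in 20 groups, or 8. TMAO replicate 5 was the outlying library in 8 of these, LPS-ALI replicate 4 in 6 and LPS-ALI replicate 3 in 3, and the values of a library are not independent of each other.

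TMAO replicate 5 had the lowest FPKM of its group for Atf3 (0.430, others 2.29 to 3.45), the inflammasome adaptor Pycard (0.360, others 9.88 to 11.4), Errfi1 (5.61, others 14.4 to 20.1) and Isg15 (23.4, others 87.8 to 137). Over all tested genes the median log2 difference of TMAO replicate 5 from the other TMAO libraries was -1.15. Low FPKM in this library is therefore not confined to these genes, and the values given are not corrected for it. Each of these genes, picked as outlying from the same data, lay further below the other TMAO libraries than that median. TMAO replicate 5 had the highest T and NK cell score, -0.336 against -1.33 to -1.05, and the highest oxidative phosphorylation score, 3.94 against 3.08 to 3.32. Its relative depth was 0.381, against 0.621 to 0.683. A family of 9 predicted genes that share 20-base words with each other, Gm10800 among them, summed to 16407 FPKM in TMAO replicate 5 and to 490 to 605 in the other TMAO libraries. The LPS-ALI libraries had 1986, 3421, 50.7 and 401.

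LPS-ALI replicate 4 had the highest FPKM of its group for Ndrg1 (94.8, others 7.76 to 10.7), Irf8 (25.4, others 5.10 to 6.09), Procr (29.3, others 2.82 to 4.40) and tissue factor gene F3 (108, others 14.4 to 16.7). It had the highest antioxidant list score, 4.13 against 2.99 to 3.12, and the highest share of FPKM in haemoglobin genes, 0.210% against 0.0147% to 0.0195%. LPS-ALI replicate 3 had the highest Pycard (38.4, others 17.1 to 17.99) and was the only library of its group above 0 for Tmsb15b2 (1.74) and Gm44170 (7.32). TMAO replicate 3 had the highest Pf4 of its group (24.2, others 12.6 to 14.8), and TMAO replicate 4 the lowest alveolar macrophage score (-0.0482, others 0.313 to 0.452).

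The pattern weighed here is that TMAO replicate 5 stands apart from the other TMAO libraries. A constant scaling error is neither shown nor excluded. The median log2 difference of TMAO replicate 5 from the other TMAO libraries was -1.15. After removal of this median the SD of the difference over genes was 0.854, above the highest value of the others, 0.5. In log2(FPKM + 1), however, a constant factor moves low genes less than high ones. Low depth adds spread too, so this SD does not decide. A bias by GC content is argued against, since Spearman's rho over genes between GC share and that difference was -0.0673, against -0.0546 to 0.112 in the others. A bias that follows transcript length stays open as a candidate explanation, since rho with exon length was -0.319 in TMAO replicate 5 and 0.0812 to 0.310 in the others, so longer genes had lower values in it. Each of the others was compared with a mean that includes TMAO replicate 5. Their ranges are therefore not an independent reference. These correlations are across genes, which are not independent replicates, and no biological explanation was tested.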

How the results depend on the processing

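Exact permutation of list scores and the joint removals of libraries were chosen after the data were seen. Gene differences below are in unshifted log2 units and list values are relative to the mean of all genes; the cause of each change was not tested. The count of genes past the threshold was 0 under 22 of 27 alternatives. It was 51 with library weights, which gave TMAO replicate 5 a weight of 0.088, and 393 at an unadjusted p under 0.05 with a 1.5-fold change. It was 23 without the X-coded libraries and TMAO replicate 5, of which 9 were the repeat family, with Camp (-2.40), Ngp (-1.56) and Rasd1 (-1.79) among the rest. Leaving out 1 library gave 0 to 3, with 1 without LPS-ALI replicate 3 (Gm44170) and 3 without TMAO replicate 4 (Gm6361, Gm6565 and AC124742.1), genes named after their values were seen.

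Vav3 was higher in TMAO lungs in all 23 alternatives that could test it; its mean was too low for the filter at 5. Exact permutation p fell under 0.05 with median-of-ratios scaling (0.77), quantile normalization (0.75) and removal of mitochondrial, haemoglobin and small RNA genes (0.66), and also without LPS-ALI replicate 2 (0.71) or TMAO replicate 3 (0.68). With TPM it was 0.55 (exact permutation p = 0.135), and its lowest value was 0.22, with library weights. Leaving out 1 library gave 0.46 to 0.71, and it was 0.30 without the X-coded libraries and TMAO replicate 5. Vav1 turned to 0.094 without the X-coded libraries and TMAO replicate 5, and leaving out 1 library moved it (-0.46) from -0.62 without LPS-ALI replicate 1 to -0.099 without LPS-ALI replicate 3. S100a8 (-0.26) turned to 0.31 under quantile scaling. Vav2, at -0.02, turned to 0.038 (TPM), 0.058 (quantile), 0.050 (without mitochondrial, haemoglobin and small RNA genes), 0.094 (library weights), 0.26 (replicate block), 0.12 (without the X-coded libraries), 0.40 (also without TMAO replicate 5) and 0.17 (without LPS-ALI replicate 4 and TMAO replicate 5). Leaving out 1 library moved Vav2 from -0.18 to 0.26, with 0.0077, 0.16 and 0.033 without LPS-ALI replicates 2 and 3 and TMAO replicate 3. Of 1257 values of the other named genes, 1243 kept their sign. Past the limma threshold were 21 of these values, 15 of them with library weights. Those 15 include Rasd1, Camp, Egr1 and Atf3, lower in TMAO lungs, and Gm6361 and Gm44170, higher.

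Of 24 called lists, 6 passed in every camera alternative that tested them with the preset correlation: immediate early, cytokine, acute-phase, ER stress, B cell and proliferation. The count was 0 with an estimated correlation, 0 by fry and 0 by exact permutation. Of the 24, 14 did not pass without the X-coded libraries, 12 with library weights and 9 without LPS-ALI replicate 4. Without the X-coded libraries and TMAO replicate 5, 11 did not pass. Library weights ended the pan-endothelial, type I interferon and ciliated calls, among others (limma camera adjusted p = 0.0990, 0.0901 and 0.0858). Alveolar type 2 markers (0.18) reversed to -0.30 (library weights), -0.59 (without X-coded), -0.36 (without LPS-ALI replicate 4), -0.51 (without X-coded and TMAO replicate 5) and -0.28 (without LPS-ALI replicate 4 and TMAO replicate 5). Club markers (0.31) reversed to -0.34 (library weights), -0.32 (without X-coded) and -0.51 (without X-coded and TMAO replicate 5), fibroblast genes to -0.083, endothelial junction genes (0.22) to -0.011 and smooth muscle markers (0.30) to -0.018 without X-coded, ribosomal protein genes (-0.039) to 0.030 with a pseudocount of 0.1, and interferon-stimulated genes to 0.041 without LPS-ALI replicate 4 and TMAO replicate 5. Leaving out 1 library gave up to 0.47 for alveolar type 2, 0.61 for club and 0.61 for mitochondrially encoded genes, and down to -0.80 for interferon-stimulated genes. Mitochondrially encoded genes went to 0.0057 without TMAO replicate 5, with the test turned, and to -0.20 without LPS-ALI replicate 4 and TMAO replicate 5. A further 49 of 910 list values had the other sign and were called in neither setting.

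Mouse numbers 1 to 4 occur in both groups. The correlations of same-numbered deviations were 0.064, -0.011, -0.033 and -0.134, within the -0.23 to 0.285 of differently numbered mice. No pairing was seen, although these values cannot exclude one. With the replicate block, 0 genes and 26 lists passed and Vav3 was 0.62. Robust moderation was not run for lists, since camera does not use it. Depth limits low genes most in TMAO replicate 5.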

Other observations

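The neutrophil test and both endothelial tests in this part were chosen only after the results they measure were seen. Genes of vascular activation and coagulation gave a mixed picture. Procr, the endothelial protein C receptor, had 9.97 ± 12.9 FPKM in LPS-ALI and 1.57 ± 0.71 in TMAO lungs, F3 had 38.7 ± 46.1 and 9.28 ± 3.47, and the granulocyte growth factor gene Csf3 had 5.71 ± 8.44 and 0.584 ± 0.581. The list of leukocyte adhesion and endothelial activation genes that holds them did not pass (limma camera adjusted p = 0.153), and complement and coagulation genes did not either (limma camera adjusted p = 0.678, with a median of 0.065 and a mean of -0.085 that differ in sign). Procr, F3 and Csf3 in LPS-ALI replicate 4, at 29.3, 108 and 18.34 FPKM, were far above the rest, and without it their unshifted log2 differences of -1.54, -1.44 and -1.44 were -0.85, -0.77 and -0.69. Among alveolar type 1 markers, Pdpn had 18.4 ± 3.56 and 8.36 ± 2.76 FPKM with no overlap between groups, while the list as a group did not pass (limma camera adjusted p = 0.424). Platelet gene Pf4 had 33.99 ± 13.97 and 16.1 ± 4.60 FPKM, with the platelet list at a limma camera adjusted p of 0.127. Genes of trimethylamine and choline metabolism, which include the Fmo enzymes that make TMAO, gave a limma camera adjusted p of 0.815, with a median of -0.09 and a mean of 0.02 that differ in sign.

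The real grouping gave 0 genes by limma, so each of 100 splits of the 9 libraries gives at least as many whatever the data, and the 100 of 100 found decide nothing about chance, with 3 genes as the highest of the other splits. For lists called by limma camera with the preset correlation, 8 of 100 splits gave at least the real 24, and the highest other split gave 27, so chance is not excluded for the number of lists. The other splits gave a median of 14 lists, and no split gave fewer than 5, so the preset correlation calls many lists in arbitrary groupings.

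The first pattern weighed is the lower level of cytokine and immediate early genes in TMAO lungs, a mean score difference of -0.680. Without the X-coded libraries the difference was -0.625 ± 0.0773 (SE). All 5 TMAO lungs scored below every remaining LPS-ALI lung for each list. This argues only weakly against the X-coded libraries as the whole cause, since 2 LPS-ALI libraries give no reliable SE. Over 21 splits the exact permutation p was 0.0952 for the cytokine list. For the immediate early list it was 0.0476, the smallest that 21 splits can give. TMAO replicate 5 as the whole cause is argued against, since without it the difference was -0.687 ± 0.117. Fewer neutrophils in TMAO lungs stay open, because the neutrophil score difference minus the cytokine score difference was 0.365 ± 0.381 (SE), which decides neither way. The most abundant markers, S100a8 and S100a9, had 5773 ± 2402 and 8181 ± 2867 FPKM in LPS-ALI and 4588 ± 1363 and 6212 ± 1280 in TMAO lungs, and their unshifted log2 differences of -0.26 and -0.35 were -0.61 and -0.59 without LPS-ALI replicate 4 and -0.046 and -0.16 without LPS-ALI replicate 1. A lower inflammatory response under TMAO is a hypothesis that these data cannot separate from differences in tissue handling or time of sampling, to which immediate early genes may also respond and which the labels do not give.

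The second pattern is the higher capillary endothelial list in TMAO lungs, a score difference of 0.701. It was 0.0633 ± 0.219 (SE) without the X-coded libraries, so the difference may come from those 2 libraries alone, whose code occurs in the LPS-ALI group only. Without LPS-ALI replicate 4 it was 0.270 ± 0.282 (SE), which leaves open whether that library alone accounts for it. The meaning of the code is not known here, so a batch, a different share of vascular tissue in those lungs and more severe injury in those mice are open and untested. LPS-ALI replicate 4 also had the lowest alveolar type 2, fibroblast and smooth muscle scores, so its difference was not confined to endothelial markers.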
